A study of Homo sapiens with 20 samples.

How the data were processed

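Single-cell gene expression was measured by droplet sequencing (10x Genomics) in 20 libraries of human gastric mucosa, 8 from source 1, 8 from source 2 and 4 from source 3. The deposited matrices hold raw counts, the number of UMIs per gene and cell barcode, in the cell-filtered form, with no normalization. The submitters' processing notes name Cell Ranger 6.1.2, STAR 2.7.2a, bcl2fastq 2.20.0 and the genome builds GRCh38 and hg38. The annotation release is not given in the sources used here. Of 36601 genes, 113 (Y-linked genes, XIST and its antisense gene) were dropped unseen before any analysis, and 34513 of the 36488 kept genes (94.59%) were found by identifier in GENCODE 29, from which coordinates are given.

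Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 40% mitochondrial UMIs, a limit set high on the premise that gastric glands are rich in mitochondria. In the cells clustered, the median share was low in parietal-like (3.93%) and chief-like cells (5.24%). It was 17.2% in neck-like and 23.1% in pit-like cells. These medians are of cells that passed the limit, so they cannot tell whether the premise holds. In the deep parietal-like cluster 29 (222 cells, median 56571 UMIs) the median share was 26.4%. Which classes lost most cells to the limit was not tested. Per library the median was 3335 to 5195 UMIs per barcode, over 2887 to 11604 barcodes. Doublet scores came from Scrublet in scanpy 1.11.5, per library. Its automatic threshold called 318 barcodes (0.451%), so the barcodes with the highest scores were called instead, at 0.8% per 1000 barcodes of the library, which gave 4384 (6.21% of kept barcodes, and 3.13%, 5.85% and 8.72% in sources 1, 2 and 3). This change was made after the scores were seen.

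Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes were chosen over libraries, leaving out the genes of all lists below and mitochondrial, ribosomal, immunoglobulin, T cell receptor and HLA genes, MALAT1, NEAT1 and genes that common deletions remove. Values were clipped at 10 SD, and 30 principal components and 20 nearest neighbours entered Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1, seed 1), with no correction for library or source. All cells gave 44 clusters, and 45749 epithelial cells, clustered again, gave 31. A cluster took the class with the highest marker score if at least 3 of its markers were detected in 5% of cells, and if its 10 leading genes held no more markers of another class than of its own. A cluster with under 1/3 of the median UMIs of its libraries also needed a marker of its own among the leading genes. Folds between clusters had 10 CPM added. The 93 markers of 19 classes and the 23 gene lists (503 genes) were fixed before the data were examined. The name signet ring-like also needed the leading genes to hold no marker of any other class. This rule was added after a first look at the clusters, and it alone left cluster 21 of the main clustering and cluster 26 of the clustering at double resolution unnamed. Also chosen after the clusters were seen were the thresholds of the naming rule, the scoring of epithelial clusters by z-score and the counting of PGA3, PGA4 and PGA5, near-identical copies, as 1 marker.

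The lists were cell junctions, mesenchymal transition, G1/S, G2/M, cell cycle arrest, p53 targets, DNA repair, ER stress, NF-kB and chemokines, dissociation response (early response genes), interferon response, antigen presentation, glycolysis and hypoxia, oxidative phosphorylation, sterol and lipid synthesis, mucin glycosylation, Wnt and stem cell, pyloric metaplasia, integrins and basement membrane, YAP targets, EGFR family and ligands, and gastric transcription factors. The results of 1 further list are not given, though it is in the counts of lists. List genes that are also markers were left out of the lists.

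The labels treat libraries as repeats within a source, so sources were the replicates for comparisons between classes. Raw counts were summed per source and epithelial class (at least 20 cells), and all classes entered 1 fit with the source as block, in edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) under R 4.3.3. For sources, counts of pit-like cells were summed per library and the 20 libraries entered 1 fit. Genes with a Benjamini-Hochberg adjusted p of at most 0.05 were called. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with fry as a further test. Lists of a class comparison were adjusted together, and those between sources over all pairs. Shares of cells per library were compared by exact two-sided permutation tests. CPM of single genes are TMM-scaled, except marker levels by class and by cluster, which are scaled by all UMIs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

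Named genes followed a rule fixed in advance. Per class comparison they were the 8 largest rises and 8 largest falls among called genes with an absolute log2 change of at least 1, the same direction in all sources and at least 20 CPM in the higher class. Left out of these were genes used for clustering, markers, mitochondrial and ribosomal protein genes, immunoglobulin, T cell receptor and HLA genes, GSTM1, GSTT1 and clone-named genes. Added to these were the 2 members with the smallest adjusted p of each called list, of which the text gives 1 or 2, and CDH1, CTNNA1 and CLDN18 throughout. Between sources only list members were named. Some genes that the rule names are not given, among them 1 of the largest rises in neck-like cells and the members of the list left out. OAS1 and ERAP2 were not named, since their levels vary with common variants. A gene with no counts is given as at least so many fold lower, with 3 counts over the cluster (the 95% limit for a count of 0) as the floor.

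No cluster was named signet ring-like or intestinal metaplasia-like, so the comparisons planned under those names were not made. Cluster 21, which only the added rule kept from the first name, was compared by number in its place, with pit-like and with neck-like cells, in a fit of its own. These comparisons, scaling to total UMIs, chief-like cells without their shallow cluster, and leaving out 3 source 1 libraries of higher mitochondrial share were chosen after the data were seen. Other settings, fixed in advance, were DESeq2 1.42.0 with its size factors, no filter on low counts, sums per library, only the 2 classes or sources compared and no source block. Cells were also taken with at most 20% mitochondrial UMIs, with at least 1000 UMIs, thinned to 1000 UMIs, and with called doublets kept. Clusters were also made at a resolution of 0.5 and of 2 and within each source. The replicate number was used as block, and each source or each source 3 library was left out in turn.

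The fits were tested on simulated data in which 200 genes were changed. In class comparisons, edgeR recovered 45.8% of genes changed by log2 1 and 83.5% of those changed by log2 2 for neck-like against pit-like cells (15746 genes fitted), 40.4% and 81.3% for chief-like against neck-like (15574), 38.9% and 74.2% for proliferating-like against pit-like (15807), and 10.8% and 39.2% for cluster 21 against pit-like cells (14833). Between sources recovery at log2 1 was 94.9% (13216 genes), 92.9% and 88.8% (13233 each), and 100% at log2 2. Of the calls on simulated data 2.04% to 5.91% were false. The simulated classes and sources differed in the 200 genes only, with as many rises as falls, so scaling was not put to the test. In the real comparisons far more genes were called, and this rate may not hold there. The slope of log2 change on truth was 1.26 for cluster 21 against pit-like cells, so these changes are overstated on average, and 0.993 to 1.01 in the other comparisons. Cluster 21 against neck-like cells was not simulated.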

Results

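The series held single-cell RNA counts from 20 droplet libraries (10x Genomics gene expression) of human gastric mucosa, the stomach lining, made to look for early signet ring cell lesions, in which mucin-filled cells lie within mucosa of normal appearance. The libraries came from 3 sources, with 8 libraries from source 1, 8 from source 2 and 4 from source 3. The labels give no treatment and no second condition, so the comparisons open to these data were those between epithelial cell classes within sources, and those between sources. The files held 132568 barcodes, with 21125443 to 100132930 UMIs (unique molecular identifiers, each standing for 1 captured transcript) per library. Source 1 libraries had 21125443 to 35287334 UMIs, those of source 2 77614562 to 100132930 and those of source 3 56170901 to 76626862. The median per barcode was lowest in source 3, at 3335 to 3822.5 UMIs per library, against 3709 to 4564 in source 1 and 4553 to 5195 in source 2. Of all barcodes, 57710 had over 40% mitochondrial UMIs, and 70549 passed the filters. After 4384 called doublets were left out, 66165 cells were clustered. Libraries of a source differed by more than the counting noise of UMIs, which the sampling of different cells alone also gives: chi-square per degree of freedom over genes was 1.92 to 6.01 in the 28 library pairs of source 1, 1.29 to 2.31 in the 28 of source 2 and 1.72 to 2.71 in the 6 of source 3.

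Clusters were named from markers fixed before the data were examined, and each name says only that a cluster resembles a type. The epithelial classes were pit-like cells, the mucous cells of the surface and foveolae marked by MUC5AC, TFF1, GKN1 and GKN2 (15462 cells, median 5319 UMIs), and chief-like cells marked by pepsinogen and LIPF (11147 cells, median 5765). Others were neck-like cells marked by MUC6, TFF2, A4GNT and LTF (2878 cells, median 16487.5), acid-secreting parietal-like cells (2672), hormone-secreting enteroendocrine-like cells (2040) and proliferating-like cells marked by MKI67 and TOP2A (1269 cells, median 5313). Other classes were endothelial-like (3753), T/NK-like (3609), plasma-like (3383), B-like (1676), smooth muscle- or pericyte-like (1373), mast-like (908), myeloid-like (785), fibroblast-like (450), glia-like (104) and erythroid-like cells (72). Clusters with 14584 cells (22.04%) met no name. Pit-like cells came mostly from different clusters in the 3 sources, namely clusters 0, 2, 16 and 17 in source 1, clusters 6 and 8 in source 2, and clusters 13, 2 and 8 in source 3. Neck-like cells lay mostly in cluster 26 in source 1, cluster 12 in source 2 and cluster 19 in source 3. Cluster 12 had the pepsinogen genes PGA3 and PGA4 among its leading genes beside MUC6, and keeps its name only because pepsinogen copies were counted as 1 marker, a choice made after the clusters were seen. Stress or immune genes were among the leading genes of some named clusters: CXCL3 in clusters 16 and 26, SOCS3 in cluster 16, ATF3 in cluster 17, IL33 in clusters 6 and 12, and DDX60 and APOL1 in cluster 2. The shallow chief-like cluster 4 (2761 cells, median 883 UMIs) was led by VIM and BPIFB1, so its name is doubtful. Of the pit-like clusters only cluster 2 had a pit marker among its leading genes, and cluster 6 was named on a score of 0.282. Cluster 16 shared CXCL3 and PPP1R1B with a cluster of all cells named neck-like. Its MALAT1 was at 14285 CPM in source 1, against 11973 in neck-like and 73616 in pit-like cells. Both names are less sure. Cluster 6 held 21613630 of the 30274832 pit-like UMIs of source 2, and cluster 16 held 21450454 of 58665757 in source 1.

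The makeup of the libraries differed between sources. Pit-like cells were 51.6% ± 2.62 of the cells of a source 1 library (SD, n = 8), 13.5% ± 1.37 in source 2 (n = 8) and 15.9% ± 1.38 in source 3 (n = 4). Pepsinogen-making chief-like cells went the other way, with 2.60% ± 0.361, 19.7% ± 1.05 and 23.2% ± 1.29. Of the 5125 chief-like cells of source 3, 2191 lay in the doubtful cluster 4, and without it the shares were 2.18% ± 0.414, 17.9% ± 1.04 and 13.3% ± 0.637, which turns the order of sources 2 and 3. Parietal-like cells were 8.06% ± 1.03 in source 1, 1.90% ± 0.177 in source 2 and 4.0% ± 0.431 in source 3, and proliferating-like cells 2.96% ± 0.668, 1.33% ± 0.218 and 1.92% ± 0.0615. Neck-like cells were 2.91% ± 0.357, 5.72% ± 0.308 and 3.60% ± 0.225, and enteroendocrine-like cells 1.43% ± 0.266, 3.94% ± 0.265 and 3.15% ± 0.375.

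Among immune and stromal classes, source 2 had the highest shares of endothelial-like cells, at 11.7% ± 1.17 against 1.13% ± 0.305 in source 1 and 1.07% ± 0.206 in source 3, and of mast-like cells, at 3.06% ± 0.355 against 0.0201% ± 0.0277 and 0.136% ± 0.129. Source 3 had the highest share of B-like cells, at 7.23% ± 0.458 against 0.0199% ± 0.0277 and 0.302% ± 0.195, and of T/NK-like cells, at 7.64% ± 0.784 against 4.66% ± 0.422 and 4.25% ± 0.307. Antibody-secreting plasma-like cells were 0.493% ± 0.211 in source 1, 7.22% ± 0.408 in source 2 and 5.64% ± 0.271 in source 3. Epithelial cells without a class name were 14.1% ± 0.796, 11.5% ± 0.995 and 21.9% ± 1.71.

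In an exact two-sided permutation test with Benjamini-Hochberg adjustment over the 54 class and pair combinations, 16 of 18 classes differed between sources 2 and 1, 14 between sources 3 and 1, and 17 between sources 3 and 2. The smallest p that libraries of these numbers can give is 0.000155 for 8 against 8 (adjusted p = 0.000699) and 0.00202 for 4 against 8 (adjusted p = 0.00273), and the pit-like and chief-like differences of source 1 from both other sources reached it. The direction of the neck-like difference between source 1 and the other sources, of the chief-like, pit-like and parietal-like differences between sources 2 and 3, and of the unnamed epithelial difference between source 1 and the others, turned with the clustering or with doublets kept. At the lower resolution the neck-like share of source 2 minus that of source 1 was -1.975 percentage points, the parietal-like share of source 3 minus that of source 2 was -0.262, and the unnamed epithelial share of source 3 minus that of source 1 was -8.218. Parietal-like cells then numbered only 79, 111 and 28 in sources 1, 2 and 3. Depth also differed between sources, and p-values between sources measure the spread between libraries of a source only, which may be technical.

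**Figure D1:**
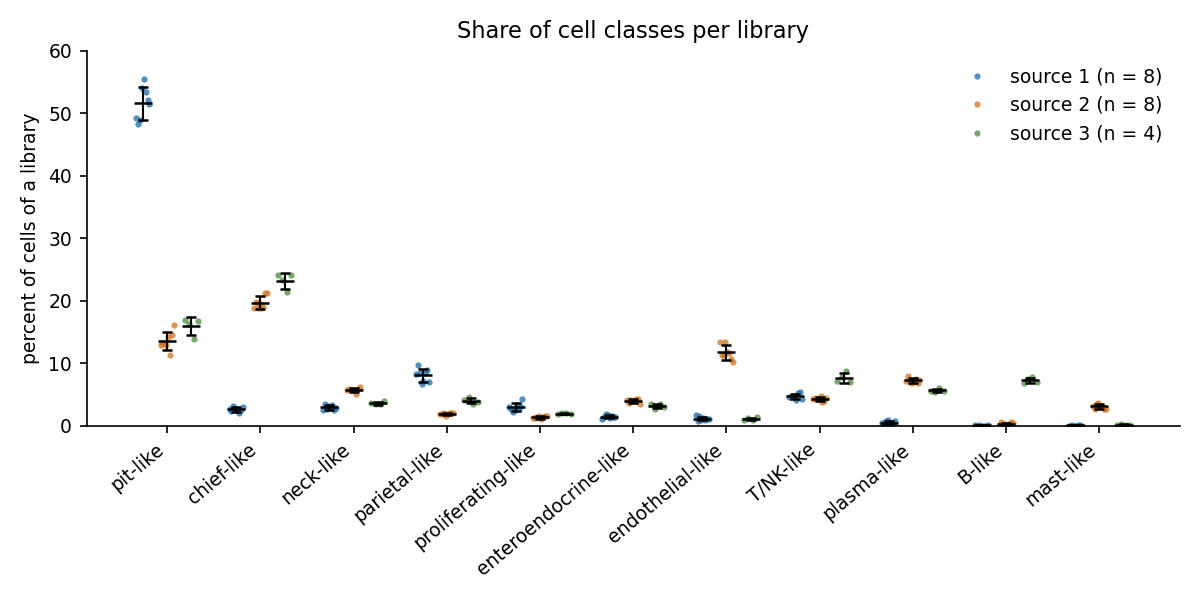
Percent of a library's cells in 11 classes (y axis), for the libraries of source 1 (blue, n = 8), source 2 (orange, n = 8) and source 3 (green, n = 4); points are libraries and black lines the mean ± SD. Pit-like shares of source 1 lie around 51.6%, above 13.5% in source 2 and 15.9% in source 3.

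Neck-like cells, the mucous cells of the upper gland, were compared with pit-like cells to see how the mucous lineages of the gland and of the surface differ. Pit-like cells here include clusters 6 and 16, whose names are less sure. AQP5, a water channel, was at 285 ± 273 CPM (counts scaled to equal library totals; SD, n = 3 sources) against 11.8 ± 10.3 in pit-like cells, and its rise was 4.65 ± 0.80 (log2 ± SE; edgeR adjusted p = 0.000272). AQP3, another water channel, rose by 4.09 ± 0.52 (adjusted p = 2.4e-05). WFDC2, a secreted protein with whey acidic protein domains, rose by 4.36 ± 0.55 from 3.18 ± 0.606 to 60.7 ± 40.5 CPM (adjusted p = 2.4e-05). The ETS-family transcription factor ETV5 rose by 4.06 ± 0.40 (51.6 ± 34.3 against 2.96 ± 1.61 CPM, adjusted p = 3.25e-06). VIM, an intermediate filament protein best known from mesenchymal cells (4.50 ± 0.66, adjusted p = 7.39e-05), HPN, a membrane serine protease (4.0 ± 0.58, adjusted p = 7.44e-05), and C16orf89 (4.10 ± 0.70, adjusted p = 0.000236) were also among the 8 rises that the naming rule gave.

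DSC2, the desmosomal cadherin desmocollin 2, was at 1.33 ± 0.589 CPM in neck-like cells and 143 ± 82.6 in pit-like cells (log2 change -6.60 ± 0.63, edgeR adjusted p = 2.74e-06). COL17A1, the transmembrane collagen of hemidesmosomes, changed by -6.38 ± 0.41 (0.431 ± 0.294 against 40.3 ± 27.3 CPM, adjusted p = 1.26e-07), and CDHR2, a cadherin of the brush border, by -6.62 ± 0.72 (adjusted p = 7.07e-06). GDA, guanine deaminase (-7.45 ± 0.71, adjusted p = 2.77e-06), CYP4F3 (-6.49 ± 0.72, adjusted p = 8.76e-06) and C6orf141 (-6.31 ± 0.31, adjusted p = 9.59e-09) fell as well. LGALS9B and LGALS9C, with changes of -6.72 and -6.71, are near-identical copies whose counts could be split between them, so their separate values are uncertain. AQP5 was also a leading gene of the neck-like cluster 26, and GDA and CYP4F3 of the pit-like cluster 13.

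Of 23 gene lists fixed in advance, 6 differed as groups (camera with a preset correlation of 0.01). Cell junction genes fell, with 15 of 25 members lower and 2 higher (median log2 change -0.80, adjusted p = 0.00063), among them PKP3, a desmosomal plaque protein (-1.65 ± 0.18). Integrin and basement membrane genes had 11 of 22 lower and 3 higher (median -0.72, adjusted p = 0.00759). G1/S genes had 13 of 23 lower and 0 higher (median -0.88, adjusted p = 0.021), such as MCM4 of the replicative helicase (-1.58 ± 0.21) and CLSPN, a checkpoint adaptor (-3.80 ± 0.46). ER stress genes, which fold and export proteins, had 15 of 24 higher and 0 lower (median 0.92, adjusted p = 0.00063), such as DNAJB9 (2.14 ± 0.33) and SEC61B of the translocon (1.5 ± 0.23). Oxidative phosphorylation genes had 22 of 31 higher and 0 lower (median 0.65, adjusted p = 0.00063), such as NDUFB9 of complex I (1.22 ± 0.20) and ATP5F1A of ATP synthase (0.98 ± 0.17). Wnt and stem cell genes had 11 of 21 higher and 2 lower (median 0.90, adjusted p = 0.00759), such as TNFRSF19 (6.59 ± 0.51) and ZNRF3, a ubiquitin ligase that removes Wnt receptors (2.5 ± 0.25). Adjusted over the list alone, 16 junction genes were lower and 2 higher, 12 integrin genes lower and 3 higher, and 23 oxidative phosphorylation genes higher, with the counts of the other 3 lists as given. Every one of these 6 calls was lost with an estimated correlation (adjusted p = 0.785 with an estimated correlation, for each).

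The other 17 lists did not pass (adjusted p = 0.112 to 0.998). They included mesenchymal transition genes (5 of 13 higher, 1 lower, median 0.72), p53 targets (2 of 20 higher, 7 lower, median -0.20), cell cycle arrest genes (5 of 19 higher, 6 lower, median 0.19), antigen presentation genes (2 of 17 higher, 7 lower, median -0.61) and EGFR family genes (5 of 18 higher, 5 lower), for which the median of -0.34 and the mean of -0.01 differed in sign from the test's direction. CDH1 (ENSG00000039068, GRCh38 chromosome 16, 68737225 to 68835548), which codes for E-cadherin, was at 66.8 ± 3.40 CPM in neck-like and 112 ± 28.7 CPM in pit-like cells (log2 change -0.76 ± 0.26, edgeR adjusted p = 0.0234). CTNNA1 (ENSG00000044115, chromosome 5, 138610967 to 138935034), for its partner alpha-catenin, changed by -1.27 ± 0.17 (79.2 ± 2.51 against 194 ± 44.4 CPM, adjusted p = 4.46e-05). CLDN18 (ENSG00000066405, chromosome 3, 137998735 to 138033655), for a tight junction claudin of the stomach, stood at -0.80 ± 0.39 and did not pass (adjusted p = 0.103).

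Over all 16860 genes tested, 4161 were higher and 4184 lower in neck-like cells (edgeR, source as block, n = 3 sources). The TMM factors raised log2 changes by a median of 0.34 over those from total UMIs, and the median gene then stood at -0.03. With scaling to total UMIs 29.4% of the called genes were higher, against 49.9% with TMM, and the number of calls was 5553 without source 3 and 4240 with cells thinned to 1000 UMIs. None of the 6 list medians changed sign under total scaling. The nuclear RNAs MALAT1 and NEAT1, which were left out of the clustering, lay lower in neck-like cells in every source, with -1.62 the difference nearest 0.

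Chief-like cells, which store digestive enzymes, were compared with neck-like cells, from which chief cells are thought to arise in the human gland. CELA3A, an elastase best known from the pancreas, had the largest rise of the genes named (8.84 ± 1.23, from 0.157 ± 0.0806 to 56.3 ± 50.5 CPM, edgeR adjusted p = 0.000221). LEPR, the leptin receptor, was at 137 ± 8.47 CPM against 19.1 ± 12 (3.23 ± 0.44, adjusted p = 0.000124), and GNMT, a methyltransferase of methionine metabolism, at 64.5 ± 5.01 against 6.53 ± 2.38 (3.35 ± 0.43, adjusted p = 7.36e-05). PDILT, of the protein disulfide isomerase family (4.15 ± 0.62, adjusted p = 0.000234), SERPINI1, a serine protease inhibitor (4.14 ± 0.37, adjusted p = 8.51e-06), the phospholipid transfer protein PLTP (3.55 ± 0.47, adjusted p = 0.000106), PKIB (3.43 ± 0.46, adjusted p = 0.000115) and PAIP2B, a translation regulator (3.32 ± 0.23, adjusted p = 1.9e-06), rose too.

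LAMB3, a laminin chain, was at 4.03 ± 0.271 CPM in chief-like cells against 47.4 ± 5.68 (-3.52 ± 0.32, edgeR adjusted p = 8.51e-06). The neutrophil chemokine CXCL3 changed by -3.95 ± 0.96 (adjusted p = 0.0059), the cytokine signalling inhibitor SOCS3 by -3.23 ± 0.50 (adjusted p = 0.000308). The Golgi membrane protein GOLM1 changed by -3.37 ± 0.38 (adjusted p = 3.6e-05) and the potassium channel KCNN4 by -3.12 ± 0.60 (adjusted p = 0.00128). The transcription factors ETV5 (-3.13 ± 0.38, adjusted p = 5.92e-05), NKX6-2 (-3.13 ± 0.65, adjusted p = 0.00224) and SOX21 (-3.12 ± 0.55, adjusted p = 0.000728) fell. CXCL3 was also a leading gene of the neck-like cluster 26 of source 1, CELA3A of the chief-like cluster 5, LEPR of cluster 10 and PDILT and PLTP of cluster 30. CTNNA1 was at 55.4 ± 6.05 CPM against 79.2 ± 2.51 (-0.52 ± 0.17, adjusted p = 0.033), while CDH1 (-0.60 ± 0.26, adjusted p = 0.0893) and CLDN18 (-0.46 ± 0.39, adjusted p = 0.394) did not pass.

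In the list tests 12 of 23 lists differed. Protein folding and energy genes stood apart on the higher side. Of the lists, 17 of 24 ER stress genes were higher and 0 lower (median 1.02, adjusted p = 6.17e-08), such as CRELD2 (2.57 ± 0.27) and SEC61B (1.82 ± 0.24). In all, 25 of 31 oxidative phosphorylation genes were higher and 0 lower (median 0.80, adjusted p = 8.57e-10), such as COX7A2 (1.43 ± 0.22) and NDUFB9 (1.29 ± 0.20). Both directions were relative to other genes, since with total UMIs the medians were -0.14 and -0.36. Mucin glycosylation genes fell, with 15 of 26 lower and 0 higher (median -1.10, adjusted p = 2.19e-06), such as the mucin O-glycosyltransferases GALNT4 (-2.44 ± 0.17) and GALNT5 (-2.05 ± 0.27). Pyloric metaplasia genes had 6 of 15 lower and 1 higher (median -1.24, adjusted p = 0.00179), such as PROM1 (-3.43 ± 0.29) and SOX9 (-1.97 ± 0.17). EGFR family genes had 10 of 18 lower and 1 higher (median -0.72, adjusted p = 2.1e-06), such as SPRED1, an inhibitor of the pathway (-2.94 ± 0.25). With an estimated correlation none of these 5 passed (adjusted p = 0.185 with an estimated correlation, except 0.273 for oxidative phosphorylation).

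Early response genes, listed because tissue dissociation induces them, had 12 of 23 members lower and 0 higher (median -1.01, adjusted p = 8.42e-06), such as ZFP36 (-1.97 ± 0.29) and KLF4 (-1.99 ± 0.31). NF-kB and chemokine genes had 8 of 19 lower and 1 higher (median -1.44, adjusted p = 0.00203), such as NFKBIZ (-2.13 ± 0.22), and interferon response genes 9 of 23 lower and 0 higher (median -0.62, adjusted p = 0.00428), such as IRF1 (-2.01 ± 0.28). With libraries as replicates (log2 ± SD, 5 CPM added, relative to the median gene), interferon genes stood at -0.17 ± 0.22, 0.08 ± 0.09 and 0.30 ± 0.10 in sources 1, 2 and 3 (n = 8, 8 and 4). NF-kB genes stood at -0.77 ± 0.38, -0.12 ± 0.07 and 0.08 ± 0.13. By this measure interferon genes did not fall in sources 2 and 3, and the NF-kB fall lay mostly in source 1. Integrin and basement membrane genes had 10 of 22 lower and 1 higher (median -0.63, adjusted p = 0.000289), such as ITGB6 (-3.03 ± 0.43), and YAP targets 5 of 15 lower and 0 higher (median -0.86, adjusted p = 0.00428), such as MYOF (-2.64 ± 0.32). Gastric transcription factors had 10 of 23 lower and 2 higher (median -0.34, adjusted p = 0.0169), such as KLF5 (-1.46 ± 0.16) and ELF3 (-2.03 ± 0.22). Junction genes had 7 of 25 lower and 0 higher (median -0.49, adjusted p = 0.0227). These calls were lost with an estimated correlation too (adjusted p = 0.185 to 0.631 with an estimated correlation). Adjusted over the list alone, 19 ER stress and 27 oxidative phosphorylation genes were higher, 13 dissociation, 10 interferon and 11 integrin genes were lower, 11 EGFR family genes were lower, 7 pyloric metaplasia genes were lower, and 8 YAP targets were lower with 1 higher.

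The remaining 11 lists did not pass (adjusted p = 0.0693 to 0.87). Median, mean and test differed in sign for 4 of them, namely mesenchymal transition (median 0.34, mean -0.15), cell cycle arrest (-0.10 and 0.10), glycolysis and hypoxia (0.19 and -0.12) and Wnt and stem cell genes (0.09 and -0.18). Over all genes, 2857 were higher and 2421 lower of 16860. Scaling mattered most here: TMM raised log2 changes by a median of 1.15 over total UMIs, with which 12299 genes passed and 2.72% of them were higher, against 54.1% with TMM. With TMM the median gene stood at -0.04, and directions are given relative to it. Without source 3 the count was 1844, without source 2 it was 3320, and with cells thinned to 1000 UMIs it was 1056.

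Proliferating-like cells were compared with pit-like cells to describe the cycling cells of the epithelium. They carried mitotic genes at levels near absent from pit-like cells. KIF23, a kinesin of cytokinesis, was at 59.7 ± 1.81 CPM against 0.180 ± 0.0255 (8.30 ± 0.41, edgeR adjusted p = 1.33e-09). The phosphatase CDC25C (8.49 ± 0.52, adjusted p = 1.19e-08), the anaphase activator CDC20 (7.84 ± 0.36, adjusted p = 7.36e-10), the kinetochore protein NUF2 (7.62 ± 0.39, adjusted p = 1.63e-09), the kinesin KIF2C (7.64 ± 0.34, adjusted p = 6.48e-10) and the mitotic kinase AURKB (7.52 ± 0.45, adjusted p = 1e-08) rose alike, as did DEPDC1 (7.82) and DEPDC1B (7.63). Lower were CDHR2 (1.81 ± 0.468 against 35.8 ± 23.5 CPM, -3.95 ± 0.65, adjusted p = 0.000443) and the membrane mucin MUC3A (-3.07 ± 0.54, adjusted p = 0.000783). So were DSC2 (21 ± 10.7 against 143 ± 82.6 CPM, -2.69 ± 0.52, adjusted p = 0.00155), the cholesterol transporter ABCG1 (-2.94 ± 0.39, adjusted p = 5.37e-05) and the cytokine IL32 (-2.93 ± 0.80, adjusted p = 0.0151). PDZD3, GDA and TCP11L2 fell by 3.62, 3.36 and 3.00 on the log2 scale. CDH1 (-0.38 ± 0.26, adjusted p = 0.312), CTNNA1 (-0.41 ± 0.17, adjusted p = 0.0976) and CLDN18 (-0.45 ± 0.39, adjusted p = 0.435) did not pass.

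All 23 G2/M genes were higher (median 6.77, camera adjusted p = 9.45e-148), and 22 of 23 G1/S genes (median 1.93, adjusted p = 6.9e-19). Members included KIF11 (5.63 ± 0.18), BUB1 (6.73 ± 0.25), RRM2 (161 ± 33.3 against 2.14 ± 1.29 CPM, 6.29 ± 0.48) and RRM1 (2.52 ± 0.19). DNA repair genes had 16 of 26 higher and 1 lower (median 0.76, adjusted p = 4.09e-11), such as the Fanconi anaemia pathway genes FANCD2 (3.56 ± 0.19) and FANCI (3.69 ± 0.25). These 3 calls held with an estimated correlation (adjusted p = 6.12e-06, 0.0258 and 0.00322 with an estimated correlation). The classes were named by other cycle genes (MKI67, TOP2A, STMN1, UBE2C, HMGB2 and TUBA1B), so a rise of cycle genes here describes the class as named. Oxidative phosphorylation genes had 19 of 31 higher and 0 lower (median 0.64, adjusted p = 1.34e-05), such as COX5A (1.10 ± 0.23). Junction genes had 9 of 25 lower (median -0.54, adjusted p = 0.00205), such as TJP3 (-1.33 ± 0.25), with 0 higher. Integrin genes had 11 of 22 lower (median -0.71, adjusted p = 0.0122), such as COL17A1 (-2.32 ± 0.33), and NF-kB genes 7 of 19 lower (median -0.80, adjusted p = 0.0329), such as IL1B (-2.44 ± 0.48), with 0 higher in either. These 4 calls were lost (adjusted p = 0.691 with an estimated correlation, for each).

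Adjusted over the list alone, 17 DNA repair and 20 oxidative phosphorylation genes were higher, and 11 junction, 12 integrin and 9 NF-kB genes were lower. The other 16 lists did not pass (adjusted p = 0.0874 to 0.573), with median, mean and test differing in sign for cell cycle arrest genes (median -0.31, mean 0.30). Over all 16860 genes, 2042 were higher and 2089 lower, so 49.4% of the calls were higher with TMM. With DESeq2's size factors that share was 59.9% and with total UMIs 69.5%, and TMM moved log2 changes by a median of -0.12 from total UMIs. The number of calls was 1074 without source 3, 2179 without source 2, 2032 with cells thinned to 1000 UMIs, 2727 without a source block and 7800 with sums per library.

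**Figure D2:**
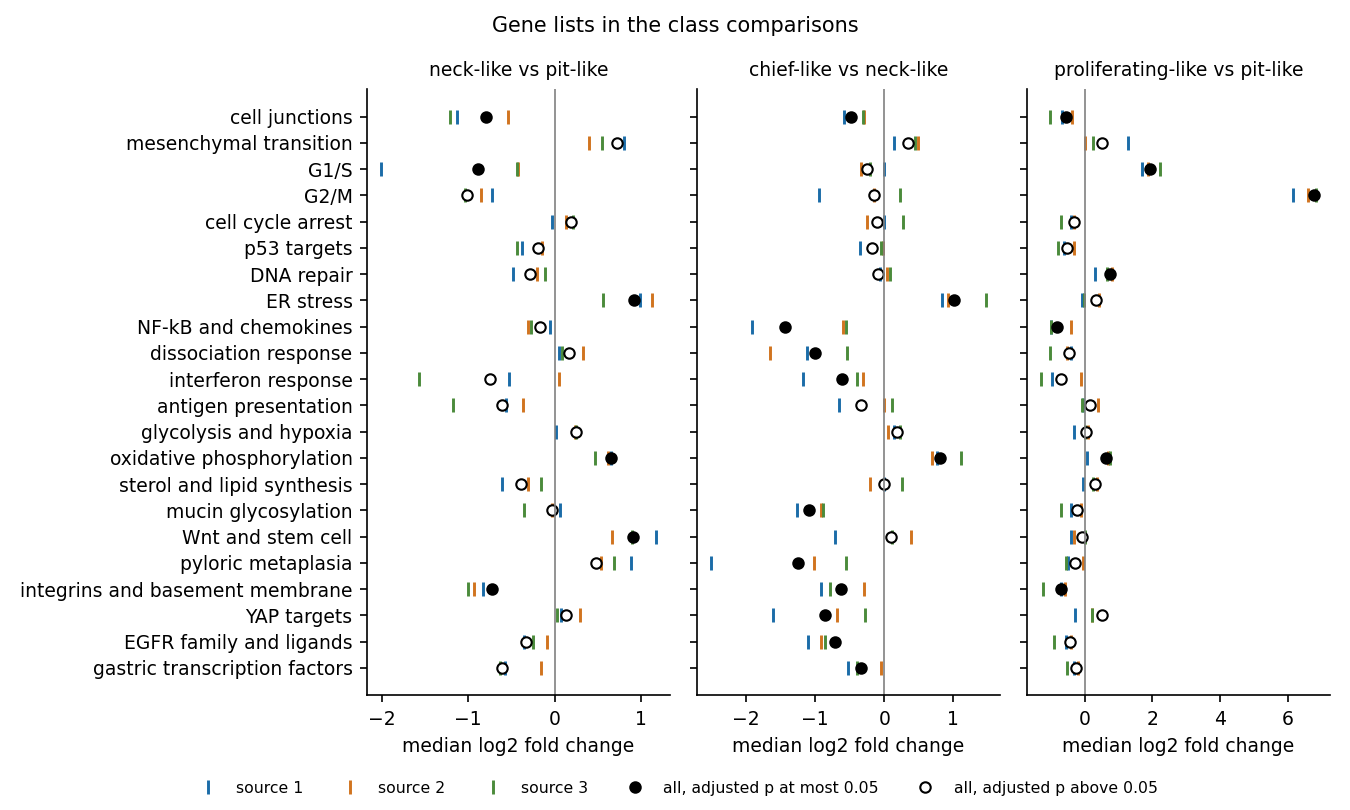
Median log2 fold change (x axis) of each of 22 gene lists (y axis) in 3 comparisons of epithelial classes. Circles are the fit over 3 sources, filled where the camera adjusted p is at most 0.05, and coloured ticks are medians within each source; G2/M genes reach a median of 6.77 in proliferating-like cells.

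No cluster was named signet ring-like or intestinal metaplasia-like, and for signet ring-like this rests on a rule added after the clusters were seen. By the rules used for all other classes, cluster 21 would have taken the name, as would cluster 26 (687 cells) at double resolution, in 2 of 5 clusterings. The added rule withheld the name where a marker of another class was among the leading genes. MUC2, CDX1 and CDX2, the intestinal mucin and the intestinal transcription factors, had 0 counts among the 1068489 UMIs of cluster 21, which allows up to 2.81 CPM. Cluster 21 (673 cells, 1.02% of all, median 1277 UMIs, 164, 72 and 437 cells in sources 1, 2 and 3) had the highest score for the signet ring markers and is given by number. It made up 1.07 ± 0.538% of cells per library in source 1 (SD, n = 8 libraries), 0.252 ± 0.0755% in source 2 (n = 8) and 1.98 ± 0.158% in source 3 (n = 4). CEACAM5 and CEACAM6 were among its leading genes, as was the pit marker GKN1. CEACAM5, GKN1, PHGR1, PSAPL1, DUOX2 and DUOXA2 led the pit-like cluster 2 as well, so they are not particular to cluster 21. Cluster 2 had the next highest signet ring score (1.12 against 1.72). Clusters 2 and 21 were not tested against each other. CEACAM5, a cell-surface glycoprotein, was at 1088 ± 854 CPM in cluster 21 (SD, n = 3 sources) against 211 ± 179 in pit-like, 1.27 ± 1.26 in neck-like and 0.614 ± 0.683 in chief-like cells. CEACAM6 was at 142 ± 133 against 24.7 ± 26.1 in pit-like cells, and MUC1, a membrane mucin, at 3214 ± 614 against 1361 ± 313 in pit-like, 677 ± 125 in neck-like and 307 ± 25.9 in chief-like cells. CEACAM6, KRT7 (30.6 ± 23.4 against 16.8 ± 12.3 in pit-like cells), REG4 (39.4 ± 54.2 against 19.8 ± 21.2) and MSLN (2.05 against 3.13) had spreads between sources as large as the difference.

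**Figure D3:**
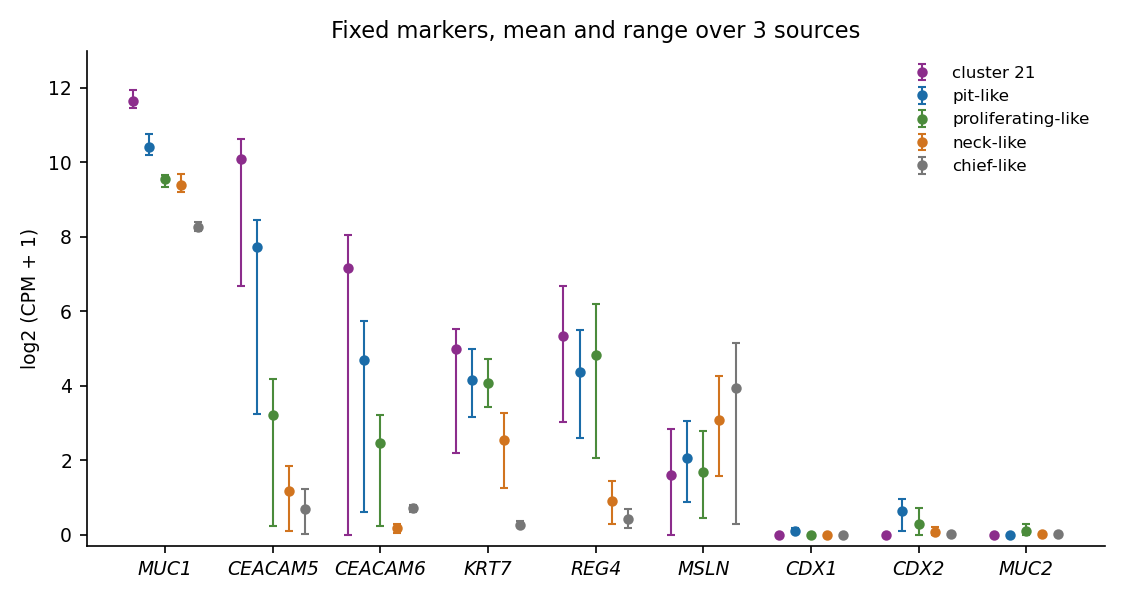
Level of 6 signet ring markers and 3 intestinal genes, as log2 of CPM plus 1 (y axis), in cluster 21 and in 4 epithelial classes; points are means over 3 sources and bars the lowest to highest source. Mean MUC1 is 3214 CPM in cluster 21 and 1361 CPM in pit-like cells, and MUC2 has 0 counts in cluster 21.

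Cluster 21 was compared with pit-like cells. In simulated data for this comparison log2 changes came out at 1.26 times the true ones over the changed genes, so its values run high on average. How far this holds for a single gene was not tested. ISG15, a ubiquitin-like interferon-induced protein, was at 349 ± 447 CPM in the cluster against 34.4 ± 36.4 (3.43 ± 0.64, edgeR adjusted p = 0.00114). IFI27 was at 3067 ± 1900 against 405 ± 258 (3.00 ± 0.65, adjusted p = 0.00334) and IFI6 at 69.5 ± 74.0 against 9.12 ± 5.28 (3.21 ± 0.68, adjusted p = 0.00266). ISG15 and IFI27 were also leading genes by which the cluster stands apart. C11orf86 (3.45 ± 0.67, adjusted p = 0.00362), the retinol dehydrogenase RDH12 (3.15 ± 0.42, adjusted p = 8.92e-05), the protease TMPRSS6 (3.27 ± 0.88, adjusted p = 0.013), the glycolytic enzyme ALDOC (2.96 ± 0.45, adjusted p = 0.000221) and IL32 (2.76 ± 0.67, adjusted p = 0.00707) rose. Among the 8 falls that the naming rule gave, 7 genes had no counts in the cluster, which with a floor of 3 counts over the cluster makes them at least 10.9-fold lower for NME1, 10.8 for C5orf63, 9.20 for ANKAR, 8.44 for RBFA, 8.08 for ZNF334, 7.47 for ADGRA3 and 7.01 for VWA2. The eighth, FAN1, had 1 count. CLDN18 was at 2430 ± 973 against 1061 ± 267 CPM (1.19 ± 0.39, adjusted p = 0.0402) and CTNNA1 at 341 ± 142 against 195 ± 42.0 (0.83 ± 0.22, adjusted p = 0.0114), while CDH1 did not pass (0.65 ± 0.30, adjusted p = 0.133). MALAT1 and NEAT1 lay lower in the cluster too in every source, with -2.02 the difference nearest 0. Against neck-like cells in sources 1, 2 and 3, MALAT1 stood at -0.14, -0.84 and -1.44 in the cluster and NEAT1 at 0.33, 1.08 and -0.85.

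Of the 23 lists 9 differed from pit-like cells, of which 1 is not given here, with medians also given with uncounted members at the floor. Junction genes rose, with 9 of 25 higher and 1 lower (median 0.69, or 0.76 with the floor, adjusted p = 4.66e-07), such as the desmosomal cadherin DSG2 (684 ± 245 against 141 ± 48.2 CPM, 2.29 ± 0.29). Integrin genes had 6 of 22 higher and 1 lower (median 0.81, adjusted p = 1.64e-05), such as COL17A1 (2.23 ± 0.29). Interferon genes had 9 of 23 higher and 1 lower (median 1.22, or 1.26 with the floor, adjusted p = 2.1e-07), such as GBP2 (1.92 ± 0.28). The pit-like cluster 2 also stood above pit-like cells as a whole for this list. Its mean log2 CPM of total UMIs was 5.59 ± 0.09 against 4.53 ± 0.09 in source 3 (SD, n = 4 libraries), and 4.56 ± 0.15 against 3.96 ± 0.07 in source 1 (n = 8). Antigen presentation genes had 5 of 17 higher and 1 lower (median 0.63, adjusted p = 0.000192), such as B2M (2.12 ± 0.39). ER stress genes had 2 of 24 higher (median 0.50, adjusted p = 0.000784), such as ATF4 (1.18 ± 0.18). DNA repair genes had 6 of 26 lower and 0 higher (median -0.75, or -0.67 with the floor, adjusted p = 0.0422), such as RAD50 (-1.07 ± 0.17). Glycolysis genes (4 of 23 higher, 1 lower, median 0.21, adjusted p = 0.0422), such as HK2 (1.90 ± 0.50), and oxidative phosphorylation genes (4 of 31 higher, 1 lower, median 0.22, adjusted p = 0.0037) passed, but their medians were -0.20 and -0.15 with total UMIs and -0.03 and -0.16 with sums per library, and the glycolysis median was -0.1 without source 3. All 9 calls were lost with an estimated correlation (adjusted p = 0.124 to 0.697 with an estimated correlation). The rises differed between sources: with libraries as replicates, interferon genes stood at 1.12 ± 0.39 in source 3 and 0.13 ± 0.24 in source 1 (log2 ± SD, n = 4 each, exact permutation adjusted p = 0.0394), and junction genes at 0.72 ± 0.06 and 0.13 ± 0.12 (adjusted p = 0.0394). Integrin genes stood at 0.64 and 0.21, and DNA repair genes at -0.43 and -1.05. Below 0 in source 1 were ER stress (0.41 and -0.10), antigen presentation (0.57 and -0.13), glycolysis (0.28 ± 0.08 and -0.32 ± 0.24) and oxidative phosphorylation genes (0.27 ± 0.10 and -0.45 ± 0.12), so the libraries of sources 3 and 1 that entered do not share the last 2 rises.

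Adjusted over the list alone, 10 junction genes were higher and 3 lower, 12 interferon, 6 antigen presentation and 7 integrin genes were higher with 1 lower in each, and 7 DNA repair genes were lower. The other 14 lists did not pass (adjusted p = 0.103 to 0.973), and the signs of median, mean and test differed for mesenchymal transition, G2/M, cell cycle arrest, sterol and lipid synthesis, YAP target, EGFR family and gastric transcription factor genes. Over 15934 genes, 1073 were higher and 2082 lower, a share of 34.0% higher with TMM, 12.4% with total UMIs and 61.8% with DESeq2's size factors. The median gene stood at -0.61 with TMM, which itself added a median of 0.42 to total scaling, so falls are given relative to a shifted median. The number of calls was 697 with at most 20% mitochondrial UMIs, 748 without source 3, 1903 without source 2 and 1738 with cells thinned to 1000 UMIs.

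Against neck-like cells, COL17A1 rose in cluster 21 by 8.62 ± 0.41 (edgeR adjusted p = 2.97e-10), DSC2 by 8.48 ± 0.64 (502 ± 250 against 1.32 ± 0.585 CPM, adjusted p = 3.89e-08) and CDHR2 by 8.71 ± 0.72 (adjusted p = 9.68e-08). ADGRF1 (8.66), TM6SF2 (8.25), SLC16A9 (8.17) and the paralogs LGALS9B (8.62) and LGALS9C (8.30), which are uncertain as above, rose too. Genes with no counts in the cluster were at least 19.3-fold lower for NME1, 16.3 for ETV5, 12.6 for GNAI1, 11.3 for TMEM132A, 10.7 for STK32B, 9.93 for VWA2, 8.29 for ADGRA3 and 6.86 for HAUS4. CDH1 (1.42 ± 0.30, adjusted p = 0.00139), CTNNA1 (2.12 ± 0.23, adjusted p = 1.38e-06) and CLDN18 (1.99 ± 0.40, adjusted p = 0.00097) rose.

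Junction genes had 16 of 25 higher and 1 lower against neck-like cells (median 1.42, or 1.71 with the floor, adjusted p = 1.21e-14), such as DSG2 (3.80 ± 0.31). A further list that passed is not given here. Integrin genes had 14 of 22 higher and 1 lower (median 1.69, adjusted p = 1.76e-12). Interferon genes had 14 of 23 higher and 2 lower (median 1.74, or 2.02 with the floor, adjusted p = 3.41e-08), such as GBP2 (4.30 ± 0.31). Antigen presentation genes had 9 of 17 higher and 2 lower (median 1.23, or 1.38 with the floor, adjusted p = 0.000489), such as TAPBP (2.09 ± 0.26). Sterol genes had 4 of 21 higher and 0 lower (median 0.34, or 0.45 with the floor, adjusted p = 0.0359), such as ELOVL6 (4.53 ± 0.36). Mucin glycosylation genes had 8 of 26 higher and 4 lower (median 0.16, but -0.06 with sums per library, adjusted p = 0.0359), such as B3GNT6 (5.07 ± 0.53). All 7 calls were lost with an estimated correlation (adjusted p = 0.12 to 0.623 with an estimated correlation). With libraries as replicates, interferon genes stood at 2.13 ± 0.44 in source 3 and 0.19 ± 0.27 in source 1 (n = 4 each, exact permutation adjusted p = 0.0394), and junction genes at 1.76 ± 0.08 and 0.74 ± 0.17 (adjusted p = 0.0394). Both again go with the smallest p that 4 against 4 libraries can give. Integrin genes stood at 1.57 and 0.72. Below 0 in source 1 were antigen presentation (1.29 and -0.21 ± 0.33), sterol (0.44 and -0.04 ± 0.16) and mucin glycosylation genes (0.57 and -0.25 ± 0.41). Adjusted over the list alone, 17 junction, 15 interferon, 10 antigen presentation and 10 mucin glycosylation genes were higher.

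The other 16 lists did not pass (adjusted p = 0.115 to 0.94), and the signs of median, mean and test differed for mesenchymal transition, G1/S, G2/M, cell cycle arrest, p53 target, NF-kB, glycolysis and EGFR family genes. Over all genes 1950 were higher and 2906 lower, 40.2% higher with TMM against 52.4% with DESeq2's size factors. The count was 2175 without source 3, 2328 with at most 20% mitochondrial UMIs and 2327 with cells thinned to 1000 UMIs.

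Pit-like cells, the class with the most cells in source 1, were compared between sources, naming only members of the fixed lists. Clusters 6 and 16, less surely named, were kept among them. The quality of these cells moved with source: their median mitochondrial share was 16.5%, 30.3% and 24.9%, and their median depth 4733, 7070 and 4761 UMIs in sources 1, 2 and 3. The list changes were not adjusted for either. ISG15 was at 97.2 ± 17.1 CPM in source 3 (SD, n = 4), 23.8 ± 3.12 in source 1 (n = 8) and 10.5 ± 2.47 in source 2 (n = 8), and IFI27 at 868 ± 37.1, 452 ± 43.2 and 223 ± 17.4. DSC2 was at 65.9 ± 7.33 CPM in source 2, 227 ± 19.8 in source 1 and 252 ± 7.21 in source 3.

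Between sources 2 and 1, 10 of 23 lists differed, of which 1 is not given here. The other 9 were lost, with 0.0897 to 0.506 as adjusted p with an estimated correlation. Junction genes (21 of 24 lower, median -0.37), G1/S genes (20 of 23 lower, median -1.01, such as MCM4, -1.22 ± 0.09), NF-kB genes (13 of 17 lower, median -0.77, such as NFKBIA, -0.98 ± 0.05) and interferon genes (15 of 23 lower, median -0.51) were lower in source 2, with 1, 2, 1 and 2 higher. So were sterol genes (12 of 20, 3 higher, median -0.23, such as SCD, -2.75 ± 0.14), antigen presentation genes (10 of 16, 2 higher, median -0.28, such as PSMB10, -0.82 ± 0.05) and integrin genes (13 of 20, 2 higher, median -0.30, such as COL17A1, -2.29 ± 0.07). Early response genes passed but went both ways (11 of 23 lower and 8 higher, median -0.02, such as HSPB1, -2.17 ± 0.05). Pyloric metaplasia genes had 9 of 14 lower and 4 higher (median -0.44), with the antioxidant enzyme GPX2 at -2.01 ± 0.05 and the alarmin IL33 at 2.06 ± 0.04. IL33 was also a leading gene of cluster 6, which holds most pit-like cells of source 2.

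Between sources 3 and 1, 9 lists differed and 3 held with an estimated correlation, and 1 of those lost is not given here. Early response genes had 20 of 23 lower in source 3 and 1 higher (median -0.76, adjusted p = 3.41e-22, and 0.0124 with an estimated correlation), such as FOSB (156 ± 6.13 against 543 ± 31.6 CPM, -1.79 ± 0.06) and ATF3 (-1.65 ± 0.07). ATF3 was also a leading gene of cluster 17, which lies almost wholly in source 1 (980 of 1011 cells). Interferon genes had 17 of 23 higher and 3 lower (median 0.52, adjusted p = 3.33e-06, and 0.0369 with an estimated correlation), such as ISG15 (2.01 ± 0.09). Plasma-like markers, looked at after the results were seen, rose in the same cells by a median of 0.82 (0.09 to 3.94 over 4 markers). Within pit-like clusters that both sources hold, the mean log2 CPM of interferon genes differed by 1.02 in cluster 2. The difference was 0.36 in cluster 16 and -0.22 in cluster 0, both looked at after the results were seen, so the rise is not shared by all pit-like clusters. Sterol synthesis genes had 15 of 20 lower and 1 higher (median -0.58, adjusted p = 5.09e-08, and 0.00893 with an estimated correlation), such as SQLE (16.5 ± 0.492 against 74.9 ± 9.22 CPM, -2.18 ± 0.09) and HMGCS1 (-1.5 ± 0.06). Junction genes (16 of 24 higher, 4 lower, median 0.24, such as CLDN7, 3.22 ± 0.20), integrin genes (12 of 20 higher, 2 lower, median 0.25), G1/S genes (20 of 23 lower, 1 higher, median -0.95), DNA repair genes (17 of 25 lower, 0 higher, median -0.38) and oxidative phosphorylation genes (20 of 31 lower, 2 higher, median -0.24) passed with the preset correlation, and were lost (adjusted p = 0.131 to 0.241 with an estimated correlation).

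Between sources 3 and 2, 8 lists differed and 4 held with an estimated correlation, of which 1 is not given here. Junction genes had 22 of 24 higher in source 3 and 1 lower (median 0.60, adjusted p = 5.54e-12, and 0.00893 with an estimated correlation), such as CGN (1.30 ± 0.06). Interferon genes had 20 of 23 higher and 1 lower (median 0.90, adjusted p = 3.99e-10, and 0.00893 with an estimated correlation). Within the pit-like clusters that both sources hold, looked at after the results were seen, their mean log2 CPM of total UMIs was no higher in source 3, at 3.22 ± 0.23 (n = 4) against 3.29 ± 0.07 (n = 8) in cluster 6 and 3.73 ± 0.16 against 3.74 ± 0.17 in cluster 8. It was 5.59 ± 0.09 in cluster 2, with 952 cells of source 3 and 6 of source 2. Integrin genes had 16 of 20 higher and 1 lower (median 0.45, adjusted p = 3.27e-06, and 0.0115 with an estimated correlation), such as COL17A1 (77.9 ± 3.98 against 12.7 ± 2.44 CPM, 2.61 ± 0.08). Early response genes (18 of 23 lower, 4 higher, median -0.51, such as EGR1, -1.70 ± 0.06), ER stress genes (14 of 24 lower, 2 higher, median -0.28, such as HSPA5, -0.94 ± 0.06), mucin glycosylation genes (12 of 25 higher and 8 lower, median 0.11, such as GCNT3, 3.42 ± 0.12) and pyloric metaplasia genes (8 of 14 higher and 4 lower, median 0.52, with IL33 at -2.87 ± 0.07) were lost (adjusted p = 0.131 to 0.254 with an estimated correlation).

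Adjusted over the list alone, the counts of members moved by at most 1 for these called lists (22 junction genes lower and 11 antigen presentation genes lower in source 2 against 1, and in source 3 against 1 18 interferon genes higher and 4 lower, 16 sterol and 18 DNA repair genes lower, and 2 G1/S genes higher). The lists that did not pass had adjusted p = 0.0837 to 0.852 for sources 2 and 1, 0.0906 to 0.91 for sources 3 and 1, and 0.0598 to 0.999 for sources 3 and 2. Median, mean and test differed in sign for mucin glycosylation, Wnt and EGFR family genes between sources 2 and 1, for cell cycle arrest, p53, antigen presentation, mucin glycosylation and EGFR family genes between sources 3 and 1, and for cell cycle arrest and EGFR family genes between sources 3 and 2.

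Over 13558 genes, 4358 were higher and 4214 lower in source 2 than in source 1 (edgeR adjusted p of at most 0.05), 3663 higher and 3632 lower in source 3 than in source 1, and 3772 higher and 4093 lower in source 3 than in source 2. Of these 979 and 605, 528 and 453, and 727 and 1025 changed at least 2-fold. With at most 20% mitochondrial UMIs, 5129 genes passed between sources 2 and 1, 5081 between sources 3 and 1 and 4611 between sources 3 and 2. Without the 3 source 1 libraries of higher mitochondrial share, 7871 genes passed between sources 2 and 1 and 6875 between sources 3 and 1. Different clusters hold most pit-like cells in each source, as listed above, and whatever batch the libraries of a source share cannot be told apart from the source.

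**Figure D4:**
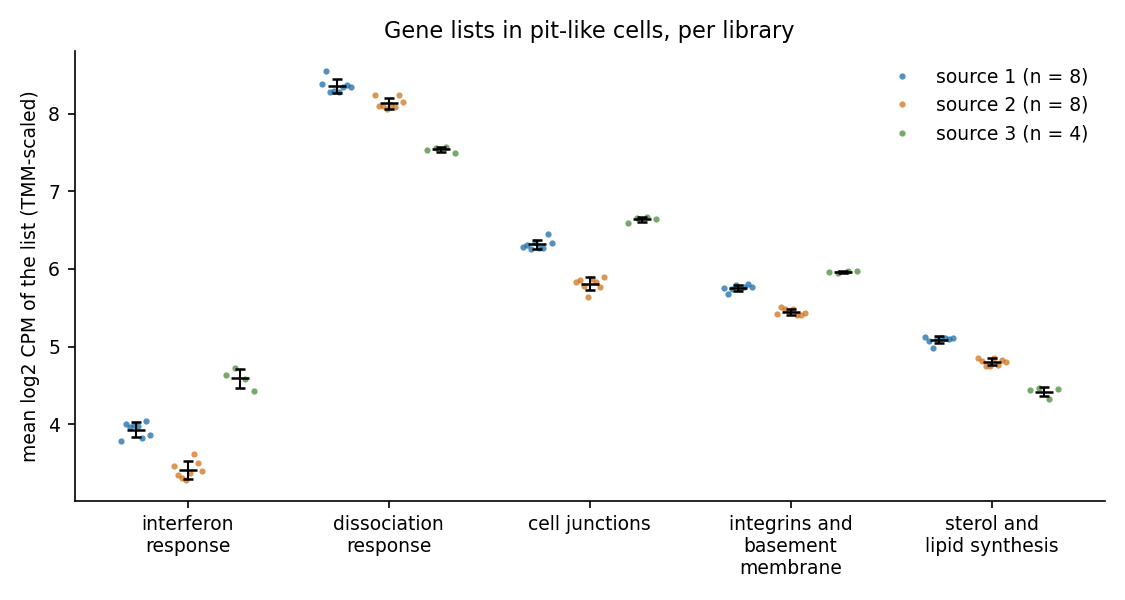
Mean log2 CPM (TMM-scaled) of the genes of 5 lists (y axis) in pit-like cells, for each library of source 1 (blue, n = 8), source 2 (orange, n = 8) and source 3 (green, n = 4), with the mean ± SD in black. Interferon response genes lie at 4.43 to 4.72 in source 3, above 3.78 to 4.04 in source 1 and 3.28 to 3.62 in source 2.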

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

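Tests chosen only after the results were seen are the thinning of cells to equal depth, the nuclear RNAs of neck-like cells, the B-like and plasma-like markers, the levels in clusters 0 and 16, the reading of T/NK-like cells, all comparisons of cluster 21 and all counts of other splits.

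Genes were lower in cluster 21, the cluster with the highest signet ring score, than in pit-like cells in 2082 cases, against 1073 higher, a balance that turned with DESeq2's size factors (61.8% of the calls higher). Among cells with at least 1000 UMIs, 59.0% of the lower genes tested in both fits stayed lower with every cell thinned to 1000 UMIs. Thinning keeps the expected share of each gene within a cell. It thus cannot tell whether what makes a barcode shallow also changes its profile, and depth per cell as a cause stays open. The test says nothing of the shallower cells left out, 67 of 164, 20 of 72 and 177 of 437 in sources 1, 2 and 3. Thinning also leaves the sums unequal, with 673 cells in the cluster and 15462 pit-like cells, so the depth of the sums stays open. A loss of nuclear RNA stays open. MALAT1 and NEAT1 lay lower in every source, with -2.02 the difference nearest 0, which met the bound written in advance for this cause. So they did in neck-like cells, with -1.62, so a low level does not by itself show a loss. Cluster 2, which shares leading genes with cluster 21, was looked at afterwards. In source 1 MALAT1 was at 10878 CPM in cluster 21 against 124910 in cluster 2, and NEAT1 at 683 against 10911. In source 3 they were at 5055 against 122360 and at 368 against 9698. This difference was not tested. No biological explanation was tested, and what else sets these barcodes apart stays open.

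Interferon response genes were higher in source 3 than in source 1 pit-like cells (mean log2 CPM of total UMIs 4.53 ± 0.0887, n = 4, against 3.96 ± 0.0728, n = 8, exact permutation adjusted p = 0.00727). Other pit-like clusters in each source could not be the whole cause, since within cluster 2 the difference was 180.5% of that over all pit-like cells, although it was -0.22 in cluster 0 and 0.36 in cluster 16. Cluster 2 itself had the immune genes DDX60 and APOL1 among its leading genes, and a different mix of cells within it was not tested. T/NK-like, myeloid-like or endothelial-like cells or their RNA are argued against, since the highest median rise of their markers was 0.06. Plasma-like markers rose by a median of 0.82 (0.09 to 3.94 over 4 markers), more than the list, and B-like markers by 0.26, so RNA of plasma-like cells may be a cause and stays open. In the other classes with enough cells the interferon rise was at most 0.22, in proliferating-like cells (exact permutation adjusted p = 0.106). It was 0.01 in T/NK-like, -0.23 in neck-like and -0.28 in parietal-like cells. This argues against RNA shared by all cells of the libraries, but not against plasma-like RNA in pit-like barcodes alone. Whatever batch the libraries of a source share cannot be told apart from the source.

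Dissociation response genes were lower in source 3 pit-like cells, at 7.57 ± 0.0328 against 8.35 ± 0.0915 (exact permutation adjusted p = 0.00727). For both explanations tested, the values met the bound written in advance for a cause, and the reading against them rests on values looked at afterwards. Composition met its bound, at -24.5% of the difference within cluster 2. Clusters 0 and 16 were lower by -0.99 and -1.63, which a change in the shares of clusters alone does not give. They hold only 7.25% and 6.43% of source 3 pit-like cells, and a different mix of cells within them was not tested. Cluster 17, at 9.02 ± 0.08 (n = 8 libraries), holds 12.1% of source 1 pit-like cells but only 29 cells of source 3. Composition thus stays open in part. A shift shared by all cells met its bound, with 85.7% of 7 other classes lower (6, of which 4 past the threshold), but T/NK-like cells were higher by 0.55 (adjusted p = 0.00727). Handling that acts on some classes only was not tested and stays open, as does batch.

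In the comparisons between classes 10 splits of 6 sums exist, too few to exclude chance. The real split gave 8345 genes for neck-like against pit-like (highest other split 1, and 1.0 split reached the real count), 5278 for chief-like against neck-like (0), 4131 for proliferating-like against pit-like (5), 3155 for cluster 21 against pit-like (0) and 4856 against neck-like cells (4). For lists other splits reached more than the real one: 8 against 6, 15 against 12, 11 against 7, 10 against 9 and 11 against 7, with 6.0, 3.0, 10, 5.0 and 5.0 splits reaching the real count. Between sources, with 30 splits of libraries drawn, the real split gave the most genes, at 8572, 7295 and 7865 against a highest other split of 1, 2142 and 0. The other splits mix libraries of 2 sources, which puts the source difference into the spread and lowers their counts. With this, and with so few splits drawn, chance spread between libraries is not excluded. As each side is 1 source, the splits say nothing of chance differences between sources. For lists chance cannot be excluded either, at 10, 9 and 8 against 11, 11 and 8, with 2.0, 4.0 and 2.0 splits reaching the real count.

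Single libraries lay far from the others of their source in 12 of 126 groups tested (chance gives about 1 in 20 groups). In source 1, replicate 2 had 1.535% smooth muscle- or pericyte-like cells (others 0.6359 to 0.9105). In source 2, replicate 6 had 0.6428% erythroid-like (others 0.0 to 0.2695), 5.066% neck-like (5.688 to 6.175) and 13.65% unnamed epithelial cells (10.38 to 11.75). In source 3, replicate 3 had 24.49% unnamed epithelial cells (21 to 21.21). As mean log2 CPM in pit-like cells, source 1 replicate 3 stood at 3.137 for G1/S (3.394 to 3.549) and 4.981 for sterol genes (5.076 to 5.128), and source 1 replicate 2 at 8.546 for dissociation response (8.275 to 8.377). Source 2 replicate 1 stood at 4.604 for EGFR family genes (4.279 to 4.42), source 3 replicate 3 at 6.254 for mucin glycosylation (6.222 to 6.225) and 4.328 for sterol genes (4.446 to 4.46), and source 3 replicate 1 at 6.633 for oxidative phosphorylation (6.544 to 6.554).

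Effects of class differed between 2 sources, by a permutation test of the difference, with means on opposite sides of 0 in 14 of 124 cases (log2, 5 CPM added, relative to the median gene). In 12 of the 14 at least 1 effect lay within its SD of 0, which leaves open whether the directions were opposite. The other 2 were glycolysis and oxidative phosphorylation for cluster 21 against pit-like cells. For chief-like against neck-like cells, NF-kB genes differed by 0.85 between sources 3 and 1 (0.08 and -0.77) and by 0.19 between sources 3 and 2 (0.08 and -0.12), and interferon genes by 0.25 between sources 2 and 1 (0.08 and -0.17) and 0.47 between sources 3 and 1 (0.3 and -0.17). For proliferating-like against pit-like cells, CDH1 differed by 0.42 between sources 2 and 1 (0.06 and -0.36) and by -0.73 between sources 3 and 2 (-0.67 and 0.06). For cluster 21 against pit-like cells, sources 3 and 1 differed by 0.51 for ER stress (0.41 and -0.1), 0.7 for antigen presentation (0.57 and -0.13), 0.6 for glycolysis (0.28 and -0.32), 0.72 for oxidative phosphorylation (0.27 and -0.45) and 1.28 for CDH1 (1.07 and -0.22). Against neck-like cells they differed by 1.5 for antigen presentation (1.29 and -0.21), 0.48 for sterol genes (0.44 and -0.04) and 0.82 for mucin glycosylation (0.57 and -0.25).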

How the results depend on the processing

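Chosen only after the results were seen were all settings of the cluster 21 comparisons, scaling to total UMIs, leaving out the shallow chief-like cluster and leaving out 3 source 1 libraries of higher mitochondrial share.

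Of 210 values that are counts, 176 stayed within 1.5 times the reported count and 34 moved further, and the cause was not tested unless given. With cells thinned to 1000 UMIs, which leaves fewer counts to test, genes passing the threshold were 4240 for neck-like against pit-like (8345 reported), 1056 for chief-like against neck-like (5278), 2032 for proliferating-like against pit-like (4131), and 1738 and 2327 for cluster 21 against pit-like (3155) and neck-like cells (4856). Depth thus limits most of these counts. With sums per library, which raises the number of sums, there were 8835 for chief-like, 7800 for proliferating-like and 5058 for cluster 21 against pit-like cells. Without a source block 2727 passed for proliferating-like cells. At 20% mitochondrial UMIs 697 and 2328 passed for cluster 21, 5129 between sources 2 and 1, and 4611 between sources 3 and 2. Scaled to total UMIs, 12299 passed for chief-like against neck-like cells, and 7.0 lists in place of 12.

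Leaving out 1 source, which leaves 2 sums per class, gave 5553 to 6408 genes for neck-like, 1844 to 4184 for chief-like and 1074 to 3563 for proliferating-like cells. For cluster 21 it gave 748 to 2120 against pit-like and 2175 to 4010 against neck-like cells. Source 3 gave the lowest count in each, and source 2 also moved the count by over 1.5 times for chief-like, proliferating-like and cluster 21 against pit-like cells. For proliferating-like lists the range was 4.0 to 8.0, lowest without source 3. With an estimated correlation between genes, no lists passed (0.0) for neck-like, chief-like and both cluster 21 comparisons, 3.0 for proliferating-like, and 1.0, 3.0 and 4.0 between sources 2 and 1, 3 and 1, and 3 and 2.

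Of 287 list values, 218 kept direction and side of the threshold, 61 no longer passed and 8 turned. Scaled to total UMIs, chief-like against neck-like medians turned to -0.14 for ER stress (1.02 reported) and -0.36 for oxidative phosphorylation (0.8), and cluster 21 against pit-like medians to -0.2 for glycolysis (0.21) and -0.15 for oxidative phosphorylation (0.22). With sums per library the latter 2 were -0.03 and -0.16, and the mucin glycosylation median against neck-like cells was -0.06 (0.16). Glycolysis ranged from -0.1 to 0.4 with 1 source left out, turning without source 3. Of 2536 values of named genes between classes, 2423 stayed, 93 no longer passed, 20 came to pass and none turned. All 578 values of named genes between sources stayed. Apart from CDH1, CTNNA1 and CLDN18, the named genes were picked from these same data. They were picked by threshold, size and shared direction or by smallest p, so this stability was largely set by the choice.

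Of 702 share differences, 593 stayed, 69 no longer passed, 4 came to pass and 36 turned. In percentage points, the turned ones of source 2 minus source 1 were fibroblast-like (-0.014 reported) at 0.008 with at least 1000 UMIs, 4.047 at the lower and 0.696 at the higher resolution, 1.694 with doublets kept and 4.239 with clusters made within sources. Neck-like (2.817) was at -1.975, -1.608, -1.345 and -1.114 under the last 4 settings. Unnamed cells (1.175) were at -1.728 at 20% mitochondrial UMIs, -0.513 at the lower resolution and -6.571 within sources, and unnamed epithelial cells (-2.611) at 8.385 with doublets kept and 2.974 within sources. For source 3 minus source 1, neck-like (0.694) was at -0.455 at 20% mitochondrial UMIs, and -3.138, -2.619, -1.45 and -3.026 under the 4 clustering settings in the same order. Myeloid-like (0.045) was at -0.044 with at least 1000 UMIs, -0.065 at the higher resolution, -0.149 with doublets kept and -0.157 within sources, and unnamed epithelial cells (7.863) at -8.218 at the lower resolution. With each source 3 library left out, endothelial-like (-0.061) ranged from -0.139 to 0.009, turning without replicate 3, and myeloid-like from -0.008 to 0.081, turning without replicate 2. For source 3 minus source 2, chief-like (3.497) was at -4.209 at the lower resolution, -3.942 with doublets kept, -2.322 within sources and -4.629 without the shallow chief-like cluster, and pit-like (2.412) at -2.95 at the higher resolution, -1.124 with doublets kept and -7.447 within sources. Erythroid-like (-0.172) was at 0.308 at the lower resolution and 0.179 with doublets kept, and parietal-like (2.105) at -0.262 at the lower resolution.

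Replicate numbers do not pair the libraries: same-number correlations were -0.154 to 0.222, and 0, 1 and 0 of 8, 4 and 4 libraries correlated best with their own number. With the number as block, no classes (0.0) passed between sources 3 and 1 or 3 and 2, where 4 libraries leave few permutations, and no other count moved by over 1.5 times.

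Alternatives for the signet ring-like and intestinal metaplasia-like comparisons were not run under those names. A rule added after a first look at the clusters withheld the signet ring name from 1 cluster in 2 of 5 clusterings, so its absence depends on that rule.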

Other observations

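The values here are for 3 clusters of epithelial cells that met no class name, chosen after the clusters were seen. Cluster 28 (346 cells, with 41, 56 and 249 in sources 1, 2 and 3, median 3429 UMIs) was led by SH2D6, LRMP, AOC1, BMX, TRPM5, AVIL and HPGDS. The ion channel TRPM5, the actin regulator AVIL and the prostaglandin D2 synthase HPGDS are known from tuft cells, a rare chemosensory type for which no markers were fixed. MUC1, a membrane mucin, was at 71.8 ± 43.6 CPM there (SD, n = 3 sources), against 1361 ± 313 in pit-like cells.

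Cluster 14 (1215 cells, with 11, 1043 and 161 in the 3 sources, median 20551 UMIs) was led by ALB, BMP3, REG4, ORM2, IL33 and SPINK1. REG4, a secreted lectin and one of the signet ring markers, was at 55.0 ± 67.0 CPM there (n = 2 sources) and MUC1 at 969 ± 70.9, while CEACAM5 was at 0.645 ± 0.292. Cluster 1 (3450 cells, median 868 UMIs) was led by ADH1C, GPX2 and LYZ, with 2337 of its cells in source 3.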
